A study of Mus musculus with 2 samples.

How the data were processed

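Trimethylation of lysine 4 of histone H3 (H3K4me3), a chromatin mark found at the starts of active and poised genes, was mapped by chromatin immunoprecipitation and sequencing in hearts of mouse embryos at day 10.5. Per the labels, replicate 1 was a pool of hearts from 69 embryos and replicate 2 a pool from 51 embryos, of both sexes and of the strain B6NCrl, with sonicated fragments in a range of 300 to 500 bp. The replicates were separate biological samples of 1 group, so the series held no contrast between conditions, and the comparisons were made between the replicates and between groups of genes within the same hearts.

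The authors deposited 4 peak lists in narrowPeak format on the mouse build mm10 (GRCm38). Per the text files deposited with the samples, the list of each replicate was made from the alignments of that replicate and 1 control, the pooled list from both replicates and both controls, and the replicated list from the pooled list and both single lists. The aligner, the peak caller, their versions and the sequencing depth were not given in the sources used here, so the depth behind each peak is unknown and no interval that needs it was computed. For each peak the authors deposited a display score, which was not used, a signal value, and −log10 of a p-value and of a q-value. The deposited signal value was used to rank or filter peaks within 1 list, and its unit was not stated. The lowest deposited −log10 p-value was 2.00 in the pooled list, and 14.4% of pooled peaks had a −log10 q-value under 2.

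Peaks were annotated with GENCODE mouse release 21 and with the GRCm38 sequence, on chromosomes 1 to 19, X and Y. No peak reached past the end of its chromosome in that build. A promoter window was 1000 bp either side of the annotated start of every transcript of a gene. A gene was called marked when a replicated peak overlapped such a window, and its signal was that of the highest such peak. Peaks were joined into domains over gaps of up to 1000 bp, and a gene took the widest domain with a peak in its windows. The CpG ratio of a gene was the highest observed over expected CpG ratio of its windows.

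The share of peaks overlapping by at least 1 bp was set against 1000 circular shifts of a list along each chromosome by at least 1000000 bp. The 25 gene lists were fixed before the data were examined, and 24 of them matched the annotation in full; Ahsp of the erythroid list had no match. Only protein-coding members were tested. Shares of marked genes, and of genes among the widest 5% of domains, were compared with all other protein-coding genes by Fisher's exact test, two-sided. Median widths and signal values of marked members were set against 10000 random lists of the same size drawn with replacement from all marked protein-coding genes, the list itself included, for lists with at least 5 marked members. Benjamini-Hochberg adjustment was made over the lists of each test, at a threshold of 0.05. The smallest unadjusted p the random lists can give is 0.0002, which became 0.0006 for widths and 0.00105 for signal values after adjustment. Differences of medians between classes of genes or peaks were tested by 100000 shuffles of the labels, which can give 1e-05 at the smallest. Genes and peaks are not replicates, so these p-values describe the 2 libraries. Intervals of shares are exact 95% binomial intervals and cover counting of peaks or genes only.

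The genes named are, for each list, up to 4 marked members with the widest domains and up to 4 unmarked members in alphabetical order, the genes of the 15 widest domains, the genes at the 5 highest peaks, and 18 landmark genes. The peaks named are the 5 highest of the replicated list, the 5 highest of each replicate with no peak of the other within 1000 bp, and the 5 highest over 5000 bp from any start. Exceptions are stated where they occur.

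The overlap and joining steps gave the counts of bedtools 2.31.1 on the same lists. The list tests were tested on simulated data. With 20 genes per list and widths multiplied by 1.5, 74% of 50 changed lists were recovered, and with widths doubled or tripled 100% were. The test of marked shares recovered 96% of 50 lists given a rate of 98%. At most 6% of unchanged lists were called. The unchanged lists were drawn at random, and for marked shares the marks were set without regard to CpG content. That rate therefore does not cover lists whose CpG content differs from that of other genes. Alternatives were the pooled list, each replicate alone, stricter peak filters, other overlaps, windows, gaps and distances, the outermost start alone, and a background matched on CpG ratio. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Peaks on unplaced sequences were left out of all comparisons.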

Results

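H3K4me3 was measured in 2 pools of embryonic mouse hearts taken at day 10.5, when the looped heart tube is forming chambers and cushions. The replicate 1 list held 45075 peaks over 44.4 Mb, and the replicate 2 list held 48518 peaks over 48.7 Mb. The pooled list held 55026 peaks and the replicated list 34577, with median widths of 478 bp and 1040 bp. All values per gene below come from the replicated list unless a replicate is named, and the depth of the libraries is unknown.

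The first question was how far the pools gave the same marked regions. Of the replicate 1 peaks on the assembled chromosomes, 76.7% (95% interval 76.3 to 77.1) overlapped a replicate 2 peak, and 67.8% (67.4 to 68.2) of replicate 2 peaks overlapped a replicate 1 peak. Circular shifts gave at most 4.25% and 3.94%. The shared peaks held 94.3% of the covered length of replicate 1 and 91.5% of that of replicate 2. Peaks found in 1 replicate were narrow, with medians of 216 bp in replicate 1 and 227 bp in replicate 2, against 851 bp and 1019 bp for shared peaks. Across 30785 shared regions the ranks of the signal values had a Spearman rho of 0.944. At the level of genes, 14946 protein-coding genes were marked in both replicates, 144 in replicate 1 alone and 242 in replicate 2 alone. Across the genes marked in both, rho was 0.917 for domain width and 0.809 for promoter signal value.

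The strongest peaks with no peak of the other replicate within 1000 bp lay above the median signal value of their list (4.58 in replicate 1, 4.72 in replicate 2) and under that of shared peaks (7.95 and 11.3). In replicate 1 the highest, with a signal value of 6.19, lay between genes on chromosome 11 from 96172996 to 96173625, 20.7 kb from a start of Hoxb13. The next ranked at 5.98 on chromosome 7 from 63873802 to 63874259, between genes. The remaining 3 lay in an intron of Cxcr5 (5.52), in an intron of Gm572 (5.39) and between genes 48.2 kb from Mark1 (5.30). In replicate 2 the highest overlapped an exon of Tenm2 on chromosome 11 from 36221380 to 36221866, with a signal value of 10.1. The others lay between genes on chromosome 7 from 35908866 to 35909297 (9.12), and on chromosome 1 from 82815846 to 82816381 (8.17) and from 164224911 to 164225212 (8.17), and at a start of Gm37145 from 172391974 to 172392555 (8.08).

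The replicated list was the subset of the pooled list that carried the replicate filter. It held 62.8% of the pooled peaks on the assembled chromosomes, and all of its 34561 peaks there matched a pooled peak in position and signal value. All 30524 pooled peaks that overlapped a peak of both replicates by 50% of either peak had been kept. A further 4037 kept peaks did not meet that overlap, so the filter was not this overlap alone, and its remaining part was not given in the sources used here. The dropped pooled peaks had a median width of 216 bp and a median signal value of 2.72, against 1041 bp and 9.76 for those kept.

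Gene starts held most of the mark. Of the replicated peaks, 54.0% (53.5 to 54.5) overlapped a promoter window, where circular shifts gave at most 10.9%, and these peaks made up 77.0% of the covered length. A further 6.84% overlapped an exon away from a start, 20.2% lay in introns and 18.9% between genes. In the highest quartile of peaks by signal value 98.7% were at a start, and in the lowest 19.4%. In all, 15034 of 21938 protein-coding genes were marked, or 68.5% (67.9 to 69.1), with 68.8% and 69.2% in replicates 1 and 2. The 5 highest peaks lay over the starts of Atxn2l, Nol9, Ssbp3, Kdm5b, which encodes an H3K4 demethylase, and Wdr43. Their signal values ran from 71.4 to 76.4, and the peak of Atxn2l spanned 126501033 to 126504427 on chromosome 7. The Nol9 peak also met the promoter window of the neighbouring gene Tas1r1 but did not reach the start of that gene.

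Regulators of heart development carried the widest domains. All 24 cardiac transcription factor genes were marked, against 68.5% of other genes (adjusted p = 0.000556, Fisher's exact test with Benjamini-Hochberg adjustment). Their median domain width was 8.76 kb, where random lists had a median of 2.36 kb and a central 95% range of 1.88 to 2.96 kb (n = 24 genes, adjusted p = 0.0006 against random lists, Benjamini-Hochberg). The single replicates gave 8.24 ± 0.0424 kb (SD, n = 2). Nr2f2, which encodes a nuclear receptor of atrial and venous identity, had the widest domain of any protein-coding gene in the replicated list at 25.4 kb, from 70345761 to 70371192 on chromosome 7, covering the whole gene. It was joined from 10 peaks there, and was 25.5 kb in replicate 1 and 21.3 kb in replicate 2. It was widest in neither, since Cirbp had 32.9 kb in replicate 1 and Gata4 25.6 kb in replicate 2. In the replicated list Hand2, needed for the right ventricle, followed with 24.3 kb from 57311724 to 57336027 on chromosome 8. This width was 24.7 kb in replicate 2 and 13.1 kb in replicate 1. The replicate 1 domain ran from 57316728 to 57329804. Further replicate 1 peaks, from 57311759 and up to 57336647, lay beyond gaps of over 1000 bp on both sides and so were not joined to it. The domain of Gata4 spanned 22.7 kb on chromosome 14 from 63231226 to 63253875 and that of Nkx2-5 spanned 19.2 kb on chromosome 17 from 26835741 to 26854939. The Gata4 domain was 17.8 kb in replicate 1 and 25.6 kb in replicate 2. Gata4 and Nkx2-5 encode partner factors of early cardiac lineages. The T-box genes Tbx2, Tbx5 and Tbx20 had domains of 16.8, 16.6 and 12.7 kb, and Isl1, a marker of second heart field progenitors, one of 9.11 kb. Of the 24 genes, 17 were among the widest 5% of domains, those of at least 5.70 kb, against 4.90% of other marked genes (adjusted p = 3.4e-16, Fisher's exact test with Benjamini-Hochberg adjustment).

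**Figure D1:**
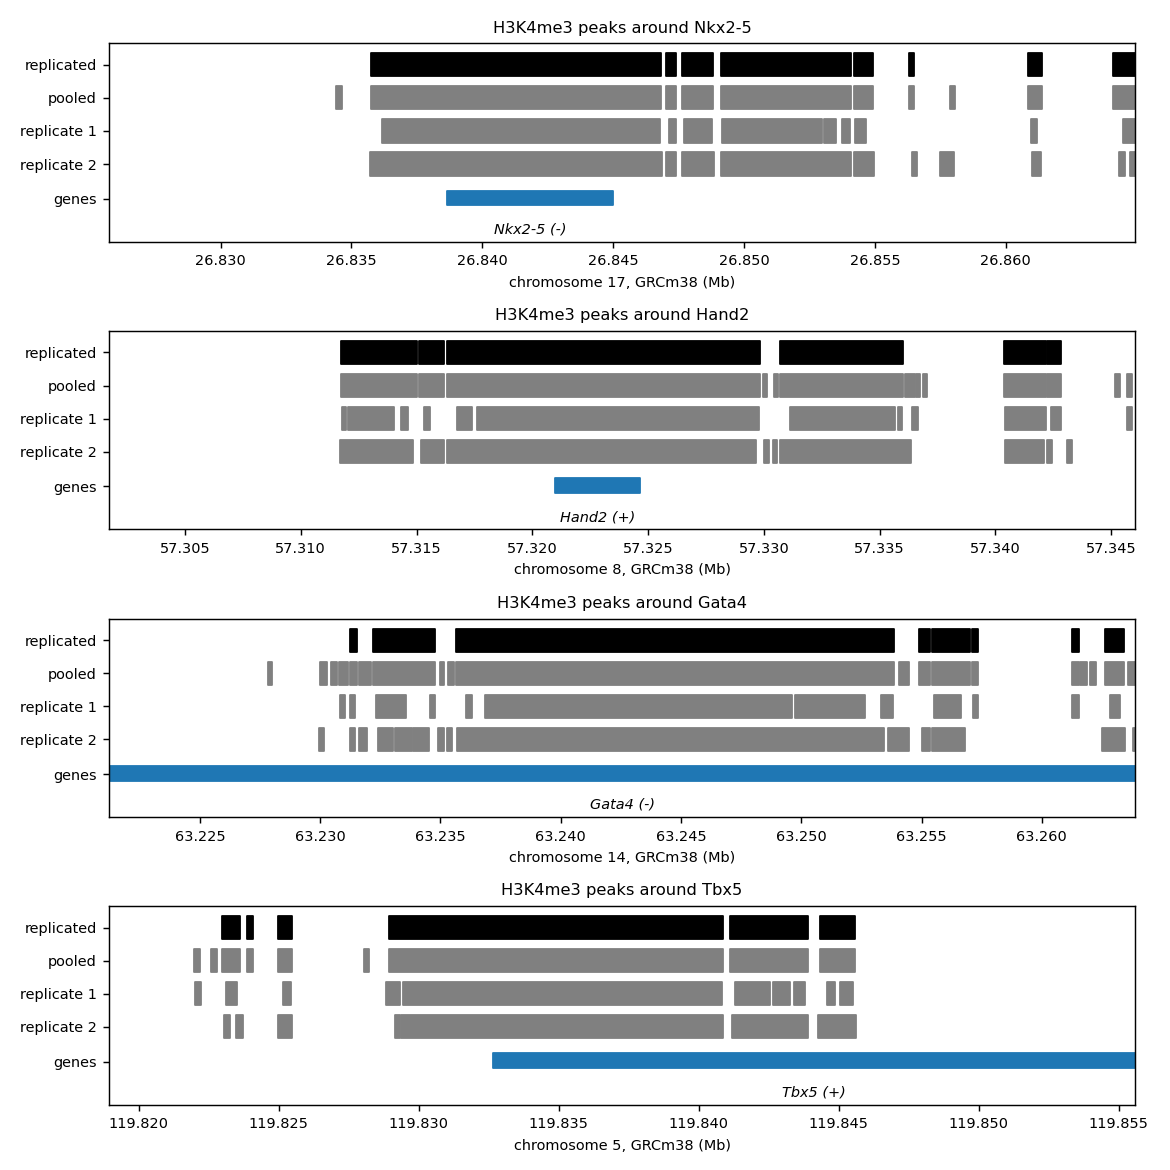
Positions of H3K4me3 peaks (bars) around Nkx2-5, Hand2, Gata4 and Tbx5 in the replicated, pooled and single-replicate lists, with protein-coding genes in blue and their strand in brackets. The x axis is the GRCm38 position in Mb. The domains of the replicated list span 19.2, 24.3, 22.7 and 16.6 kb.

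Genes of the contractile apparatus were marked as a group and in wide domains. All 24 sarcomere genes were marked (adjusted p = 0.000556, Fisher's exact test with Benjamini-Hochberg adjustment), with a median width of 6.57 kb (adjusted p = 0.0006 against random lists, Benjamini-Hochberg). The single replicates gave a median of 6.02 ± 1.08 kb (SD, n = 2). Myh6 and Myh7, the adjacent genes of the cardiac myosin heavy chains on chromosome 14, had domains of 12.4 kb from 54956532 to 54968924 and 11.5 kb from 54986418 to 54997886. Actc1, cardiac actin, had 10.2 kb from 114048483 to 114058688 on chromosome 2. Tnni3, the cardiac troponin I gene, had 9.77 kb, but 4.43 kb and 4.92 kb in the single replicates. Tnnt2 had 6.54 kb and Myl7, the atrial myosin light chain, 3.82 kb. Of the list, 16 genes were among the widest 5% (adjusted p = 7.1e-15, Fisher's exact test with Benjamini-Hochberg adjustment). The calcium handling and conduction list had 18 of 20 genes marked, which did not pass the test (adjusted p = 0.0668, Fisher's exact test with Benjamini-Hochberg adjustment) but did in the pooled list, without replicate 1 and with windows of 500 bp, and a median width of 4.38 kb, which did (adjusted p = 0.0006 against random lists, Benjamini-Hochberg). Its widest domains were those of Slc8a1, the sodium-calcium exchanger (12013 bp), Atp2a2, the calcium pump of the sarcoplasmic reticulum (8.29 kb), Pln, its inhibitor (7.48 kb), and Jph2 (7.20 kb). Nppa, the atrial natriuretic peptide gene, had 2.38 kb. Casq2 and Sln were unmarked. The width of Slc8a1 was 7.80 kb in replicate 1 and 13.7 kb in replicate 2.

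Genes of mature cardiac metabolism were marked in full, 20 of 20 (adjusted p = 0.00174, Fisher's exact test with Benjamini-Hochberg adjustment), at widths in the middle of those of random lists. Replicates 1 and 2 had 20 and 19 of these genes marked. Their median width was 2.35 kb in the replicated list, at percentile 48.3 of random lists. Esrrg, an orphan nuclear receptor gene, had the widest at 6.83 kb, followed by Ppargc1a (4.61 kb), Myh7b (3.83 kb) and Slc2a4 (3.81 kb). Myh7b, kept in this list as it was fixed, is a myosin heavy chain gene and not one of metabolism. In a comparison chosen after the values were seen, sarcomere domains were 4.22 kb wider at the median than those of this list (adjusted p = 5e-05, the smallest this permutation test can give after Benjamini-Hochberg adjustment over 5 such comparisons).

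The lists of endocardium, cushion mesenchyme, second heart field and signalling genes were marked in full. The mark was mapped in hearts and not in sorted cells, so these marks were not assigned to a cell type. All 24 genes of endocardium and endothelium were marked (adjusted p = 0.000556, Fisher's exact test with Benjamini-Hochberg adjustment), with a median width of 3.70 kb (adjusted p = 0.000933 against random lists, Benjamini-Hochberg). Nfatc1, a regulator of valve endocardium, had a domain of 8.91 kb on chromosome 18 from 80706969 to 80715881, followed by Npr3 (8.43 kb), Tal1 (8.30 kb) and Dll4 (7.58 kb). All 20 genes of cushion mesenchyme and neural crest were marked (adjusted p = 0.00174, Fisher's exact test with Benjamini-Hochberg adjustment), with a median width of 5.35 kb and domains of 9.58 kb at Pdgfra, 9.05 kb at Foxc2, 8.31 kb at Msx1 and 7.92 kb at Foxc1. The Msx1 domain was 3.74 kb in replicate 1 and 8.14 kb in replicate 2. All 18 genes of the second heart field and outflow tract were marked (adjusted p = 0.0026, Fisher's exact test with Benjamini-Hochberg adjustment), with a median of 4.44 kb, led by Hoxa1 (14.6 kb), Foxf1 (10.6 kb), Wnt5a (8.19 kb) and Nrp1 (8.17 kb). The Foxf1 domain was 11.8 kb and 6.70 kb in replicates 1 and 2. Both medians were above random lists (n = 20 and n = 18 genes, adjusted p = 0.0006 for both, Benjamini-Hochberg). Among signalling ligands and inhibitors all 22 were marked (adjusted p = 0.00082, Fisher's exact test with Benjamini-Hochberg adjustment) with a median of 4.05 kb (adjusted p = 0.0006 against random lists, Benjamini-Hochberg); Smad7 had 14.9 kb, Smad6 9.53 kb, Bmp5 8.23 kb and Bmp7 7.97 kb. Smad6 and Smad7 encode inhibitors of BMP and TGF-beta signalling. The Smad7 domain was 10.1 kb and 9.94 kb in replicates 1 and 2, and that of Bmp5 4.50 kb and 8.14 kb.

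The epicardium and smooth muscle lists did not pass the test of marked shares. Epicardium had 12 of 14 genes marked (adjusted p = 0.284, Fisher's exact test with Benjamini-Hochberg adjustment) with a median width of 2.25 kb. Wt1 had 12019 bp on chromosome 2 from 105122778 to 105134796, but 6.25 kb and 8.51 kb in the single replicates; Tcf21 had 7.43 kb, Tbx18 7.07 kb and Lrrn4 3.18 kb, and Aldh1a1 and Msln were unmarked. The endothelial median was 1.45 kb above the epicardial one, which did not pass in a comparison chosen after the values were seen (adjusted p = 0.163, permutation test with Benjamini-Hochberg adjustment). Smooth muscle had 10 of 10 genes marked (adjusted p = 0.0512, Fisher's exact test with Benjamini-Hochberg adjustment), with domains of 5.25 kb at Smtn, 4.81 kb at Des, 3.80 kb at Tagln and 3.53 kb at Synpo2. Its median width of 2.80 kb did not pass (n = 10 genes, adjusted p = 0.482 against random lists, Benjamini-Hochberg). The smooth muscle share passed without replicate 1, with windows of 500 or 2500 bp and with the outermost start alone.

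**Figure D2:**
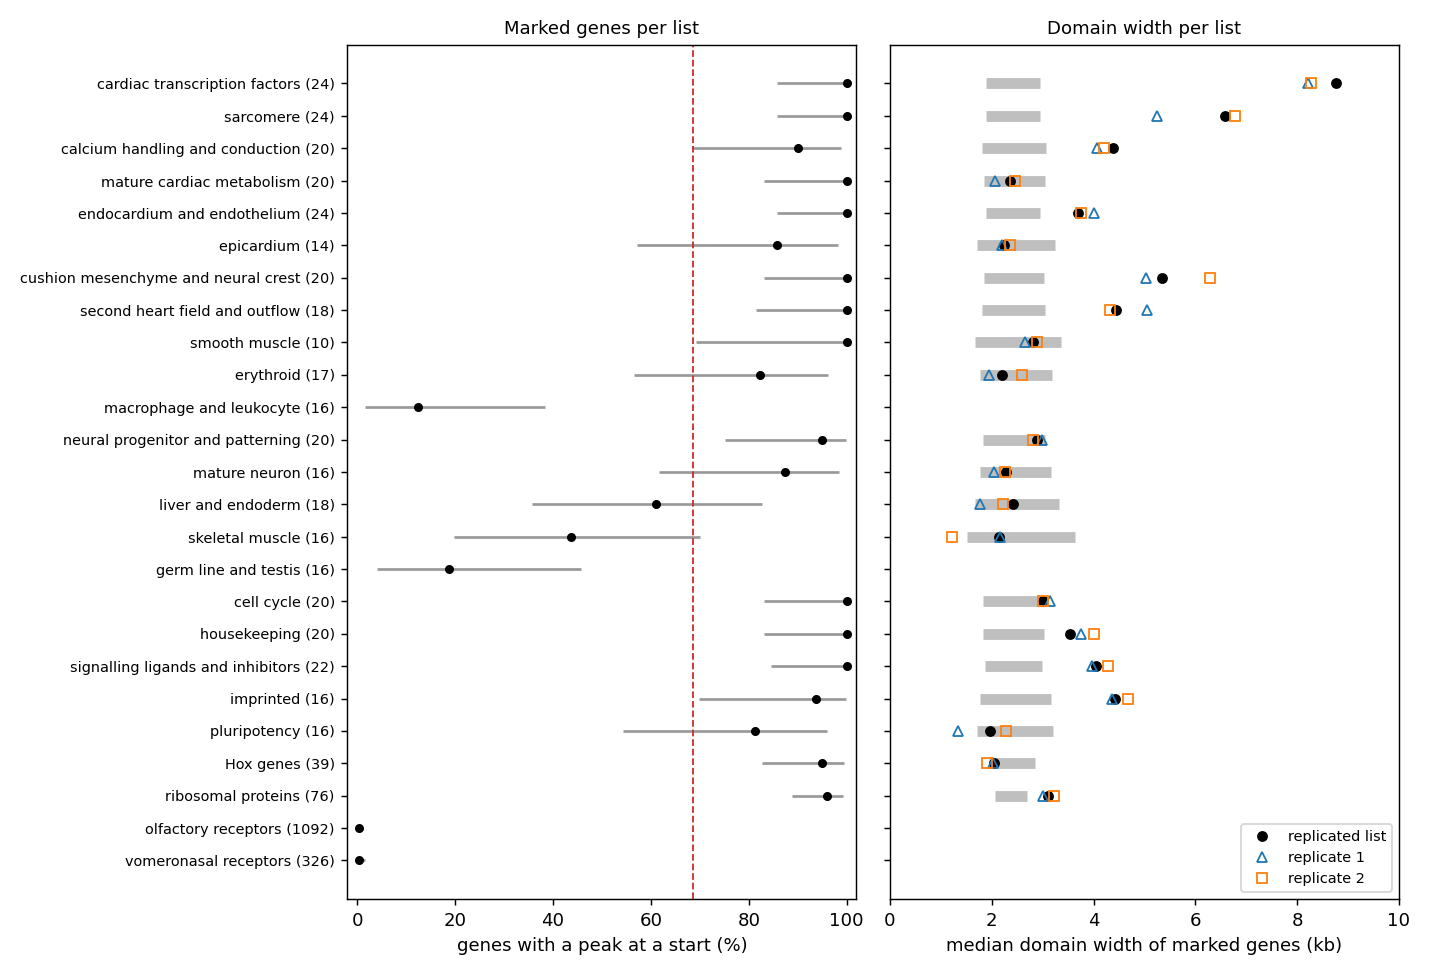
Left, share of protein-coding members with a peak at a start for each of the 25 gene lists (number of genes in brackets), with exact 95% intervals; the dashed line is the 68.5% of all protein-coding genes. Right, median domain width in kb of the marked members in the replicated list and in each replicate, with the central 95% of random lists as grey bars; cardiac transcription factors stand highest at 8.76 kb. Lists with under 5 marked members have no width.

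Genes of blood and of other organs differed from one list to another. In the erythroid list 14 of 17 genes were marked (adjusted p = 0.325, Fisher's exact test with Benjamini-Hochberg adjustment), among them Tal1 (8.30 kb), Slc4a1, an anion exchanger of red cells (4.83 kb), Epor (3.87 kb) and Tfrc (3.50 kb). Replicates 1 and 2 had 12 and 15 of the 17 marked. The embryonic globin gene Hbb-bh1 had a domain of 1.55 kb with a signal value of 3.72, and was 0.360 kb wide in replicate 1 and 1.65 kb in replicate 2. Hbb-y, Hba-a1 and Hba-a2 were unmarked; the near-identical copies Hba-a1 and Hba-a2 are uncertain, since reads they share can be lost in alignment. Macrophage and leukocyte genes were marked less often than other genes, 2 of 16 (adjusted p = 3.5e-05, Fisher's exact test with Benjamini-Hochberg adjustment), Cd14 with 1.66 kb and Spi1 with 0.298 kb (0.489 kb in replicate 1), while Adgre1, Aif1, C1qa and C1qb were unmarked. The erythroid share was above the macrophage share (adjusted p = 0.000143, Fisher's exact test with Benjamini-Hochberg adjustment), in a comparison chosen after the values were seen.

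Neural progenitor and patterning genes were marked in 19 of 20 cases (adjusted p = 0.0115, Fisher's exact test with Benjamini-Hochberg adjustment), all but Dbx1. Irx3 had 9.79 kb, Lhx2 7.71 kb, Olig2 5.73 kb and Gbx2 5.41 kb; Lhx2 had 2.32 kb in replicate 2, and Olig2 and Gbx2 had 3.13 and 3.04 kb in replicate 1. Pax6, a regulator of eye and forebrain, had 4.72 kb. Their median width of 2.89 kb did not pass the test (n = 19 genes, adjusted p = 0.213 against random lists, Benjamini-Hochberg), but was called wider at a gap of 3000 bp. The cardiac transcription factors were 5.88 kb wider at the median (adjusted p = 0.000425, permutation test with Benjamini-Hochberg adjustment), again a comparison chosen after the values were seen. Mature neuron genes were marked in 14 of 16 cases (adjusted p = 0.136, Fisher's exact test with Benjamini-Hochberg adjustment), with Gad1, Gria2, Slc17a7 and Gad2 at 3.39, 3.04, 2.82 and 2.78 kb and Slc17a6 and Th unmarked; Gad1 had 7.58 kb in replicate 2 and Slc17a7 0.927 kb in replicate 1. The mature neuron share passed without replicate 1 and with windows of 2500 bp. Liver and endoderm genes were marked in 11 of 18 cases (adjusted p = 0.612, Fisher's exact test with Benjamini-Hochberg adjustment), and in 13 and 9 in replicates 1 and 2. The marked members included Foxa1 (5.17 kb), Nkx2-1 (3.74 kb), Foxa2 (3.57 kb) and Foxa3 (3.24 kb), with 2.22 kb at Foxa1 in replicate 2. The serum protein genes Alb, Afp and Fgb were unmarked in both replicates as well, and Apoa2 had a peak of 0.282 kb in replicate 1 alone.

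Skeletal muscle genes were marked in 7 of 16 cases, which did not pass the test (adjusted p = 0.0682, Fisher's exact test with Benjamini-Hochberg adjustment). Mylpf had 3.71 kb, Acta1 3.64 kb, Myod1, the myogenic regulator, 2.21 kb and Actn3 2.14 kb; Chrna1, Myf5, Myh3 and Myh8 were unmarked. The Mylpf domain was 6.80 kb in replicate 1. The lower share passed the test with only peaks at or above the median signal value, with windows of 500 or 2500 bp and without receptor genes in the background, while genes of the same CpG decile were marked in 42.2% of cases. The sarcomere share was 56.3 percentage points above it (adjusted p = 0.000105, Fisher's exact test with Benjamini-Hochberg adjustment), also chosen after the values were seen. Germ line genes were marked less often than others, 3 of 16 (adjusted p = 0.000294, Fisher's exact test with Benjamini-Hochberg adjustment), namely Gdf9 (2.38 kb), Dazl (1.12 kb) and Ddx4 (0.572 kb), with Acrv1, Mael, Oosp1 and Prm1 among those unmarked. In the single replicates 5 and 4 of the 16 were marked. Of 1092 olfactory receptor genes 4 were marked, Olfr94, Olfr56, Olfr658 and Olfr1033. Of 326 vomeronasal receptor genes, Vmn1r4 was the 1 marked, with 5.18 kb. These families hold many close copies to which reads can fail to map uniquely. The Vmn1r4 domain lay mostly upstream of the gene and covered 2.85% of it. The CpG ratio of Vmn1r4 was 0.755, against a median of 0.123 for its list. The Gdf9 domain also lay mostly upstream of its gene. A peak counts for every window it meets, and whether these marks belong to neighbouring starts was not tested.

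Genes used by most cells were marked nearly throughout. Cell cycle and housekeeping genes were marked in 20 of 20 cases each (adjusted p = 0.00174, Fisher's exact test with Benjamini-Hochberg adjustment), and ribosomal protein genes in 73 of 76 (adjusted p = 2.7e-08, Fisher's exact test with Benjamini-Hochberg adjustment), with Rpl10l, Rpl39l and Rpl3l unmarked. The ribosomal list was drawn by a pattern of gene names that took in names ending in l. Those unmarked members therefore need not be genes used by most cells. Median widths were 3.53 kb for housekeeping genes (n = 20, adjusted p = 0.00588) and 3.11 kb for ribosomal protein genes (n = 73, adjusted p = 0.0006), both against random lists with Benjamini-Hochberg adjustment, and 3.01 kb for cell cycle genes, which did not pass (n = 20, adjusted p = 0.105). The housekeeping call was lost when the outermost start of each gene alone was used, and cell cycle genes were called wider without replicate 2 and at a gap of 0 bp. Tubb5, Actb, Gapdh and Hmbs had 8.82, 7.88, 7.16 and 5.51 kb, and Tubb5 5.45 kb in replicate 1. Ccnd2, Ccnd1, Mki67 and Plk1 had 8.36, 6.48, 4.36 and 3.90 kb. Rpl13a and Rps11 shared a domain of 8.92 kb, and Rpl36 and Rpl35 had 7.34 and 7.17 kb.

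Hox genes were marked in 37 of 39 cases (adjusted p = 0.000402, Fisher's exact test with Benjamini-Hochberg adjustment), with Hoxc11 and Hoxc12 unmarked. Hoxa1 and Hoxa2 shared 14.6 kb, Hoxb2 had 7.33 kb and Hoxb3 6.45 kb; in the single replicates the domain of Hoxa1 and Hoxa2 reached 24.2 and 23.9 kb, and that of Hoxb3 was 3.38 kb in replicate 2. Imprinted genes were marked in 15 of 16 cases (adjusted p = 0.0441, Fisher's exact test with Benjamini-Hochberg adjustment), all but Ndn, with a median width of 4.42 kb (adjusted p = 0.000933 against random lists, Benjamini-Hochberg). Igf2r had 12.8 kb, Igf2 12.4 kb, Grb10 7.64 kb and Peg3 6.74 kb. Pluripotency genes were marked in 13 of 16 cases (adjusted p = 0.437, Fisher's exact test with Benjamini-Hochberg adjustment). Tbx3, also a cardiac factor, had 8.42 kb, Sall4 5.85 kb, Lin28a 4.78 kb and Klf4 4.75 kb, while Nanog, Pou5f1 and Dppa5a were unmarked; Pou5f1 had a domain of 1.40 kb in replicate 1 alone.

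Over all lists, 13 of 25 were marked more often and 4 less often than other genes, 10 of 21 had wider domains and 0 narrower ones, also at an unadjusted p under 0.05. In the widest 5% of domains 10 of 21 lists were over-represented, besides those above the calcium (7 of 18), second heart field (7 of 18), cushion (9 of 20), endothelial (6 of 24), signalling (6 of 22), imprinted (5 of 15), epicardial (3 of 12) and ribosomal (9 of 73) lists. Signal values ran otherwise. Ribosomal protein genes were higher than random lists, with a median of 50.9 against 40.1 (n = 73 genes, adjusted p = 0.00105, Benjamini-Hochberg). The medians of 13 lists were lower, among them Hox genes at 11.9 (n = 37, adjusted p = 0.00105), sarcomere genes at 24.6 (n = 24, adjusted p = 0.00577) and neural progenitor genes at 20.6 (n = 19, adjusted p = 0.00168), by the same test. The lowest medians were those of erythroid genes at 7.53 and skeletal muscle genes at 8.36.

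The background of like CpG content changed the calls of marked shares more than those of widths. For the marked shares of the other lists it kept the olfactory and vomeronasal receptor genes, which were nearly all unmarked and lay mostly in the lowest 3 deciles. Against genes of the same CpG decile, 6 of the 17 calls were kept. They were those of sarcomere genes (100% against 54.7%), cardiac metabolism (100% against 67.8%), endothelium (100% against 82.5%), germ line genes (18.8% against 60.1%), olfactory receptors (0.366% against 9.74%) and vomeronasal receptors (0.307% against 3.88%). Calcium handling (18 of 20 genes against 71.7%), smooth muscle (100% against 58.1%) and erythroid genes (82.4% against 38.3%) passed there. The calls of cardiac transcription factors (100% against 95.5%), cushion, second heart field, neural progenitor, cell cycle, housekeeping, signalling, imprinted, Hox, ribosomal and macrophage genes were lost. All 10 calls of wider domains were kept and smooth muscle was added (2.80 kb against 1.61 kb), and the lower signal values of sarcomere, epicardial, smooth muscle and erythroid genes were not. With only peaks at or above the median signal value, the marked shares of metabolism, cushion and Hox genes no longer passed, and that of imprinted genes did not in the pooled list, with the outermost start alone or with olfactory and vomeronasal receptor genes left out of the background. Without a match on CpG ratio, erythroid genes were marked less often than other genes under that signal filter (difference -29.0 percentage points, adjusted p = 0.0311, Fisher's exact test with Benjamini-Hochberg adjustment). At a gap of 3000 bp the calls of cardiac transcription factor, sarcomere, cushion and second heart field genes in the widest 5% remained, and in the widest 1% those of cardiac transcription factor and sarcomere genes did. The epicardial call in the widest 5% was also lost without replicate 2, and the epicardial and ribosomal calls were lost with the signal filter, at a gap of 0 bp and in the widest 10%; the ribosomal call was lost at −log10 q of at least 5 as well.

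Outside the lists, the 15 widest domains included Bahcc1 (18.9 kb), Aspdh with Josd2 (17.8 kb), Cirbp (15.7 kb), Phospho1 with Abi3 and Gngt2 (15.5 kb), Tnrc18 (15009 bp), Meis2, a homeobox cofactor gene (14.8 kb), Hspg2 (14.7 kb) and Zfp503 (14.6 kb). The Cirbp domain was 32.9 kb in replicate 1 and 12.9 kb in replicate 2, and that of Hspg2 4.88 kb and 9.97 kb. Over Phospho1 the replicates gave 15.1 kb and 2.26 kb, and over Abi3 and Gngt2 15.1 kb and 8.43 kb. In all, 83 protein-coding genes had a domain of at least 10 kb, against 92 and 93 in replicates 1 and 2 and 168 in the pooled list.

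X-linked genes were marked less often than autosomal ones. Of 948 X-linked protein-coding genes 53.0% (49.7 to 56.2) were marked, against 69.8% (69.2 to 70.4) of 20807 autosomal genes (p = 2.9e-26, Fisher's exact test, two-sided). Autosomal genes weighted to the CpG deciles of the X-linked genes gave 58.7%, a smaller difference that was not tested. Without olfactory and vomeronasal receptor genes the shares were 53.5% on X and 75.1% on autosomes, a larger difference that was not tested either. On the Y chromosome 4 of 183 genes were marked, Kdm5d, Eif2s3y, Uty and Ddx3y, with domains of 1.17, 1.81, 1.61 and 1.80 kb; these were named after their values were seen. Embryos of both sexes had been pooled in each replicate. Genes with close copies, to which reads can fail to map uniquely, were not set apart on X or Y.

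Marked promoters were rich in CpG. The median CpG ratio was 0.627 at marked and 0.180 at unmarked genes, and the median GC content 55.2% and 44.2% (p = 1e-05 for both, permutation test, the smallest it can give). The marked share was 0.820% in the lowest decile of the ratio, 64.6% in decile 4 and 99.8% in the highest. Olfactory and vomeronasal receptor genes, to which reads can fail to map uniquely, were kept in these deciles. The median domain width was 0.992 kb in decile 2 and 3.22 kb in the highest, and 1.83 kb over the 18 marked genes of the lowest.

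**Figure D3:**
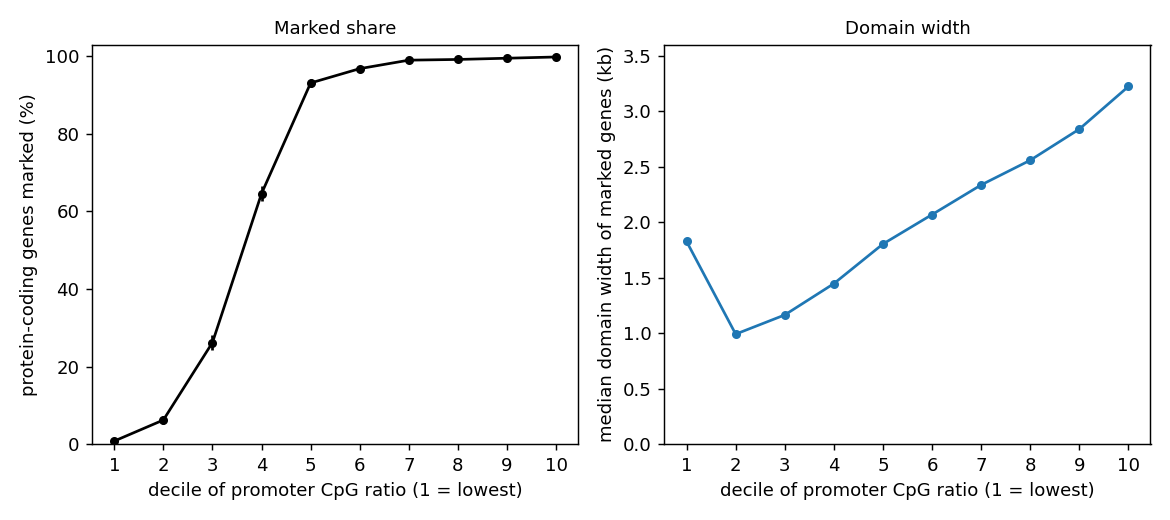
Share of protein-coding genes marked, in percent with exact 95% intervals (left), and median domain width of marked genes in kb (right), for each decile of the promoter CpG ratio from lowest to highest. The share runs from 0.820% to 99.8%.

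Peaks away from gene starts were weaker and narrower. Of the replicated peaks 10242, or 29.6% (29.2 to 30.1), lay over 5000 bp from any annotated start. Their median width was 584 bp against 1870 bp for peaks at starts, and their median signal value 4.46 against 32.3 (p = 1e-05 for both, permutation test, the smallest it can give). The strongest lay on chromosome 14 from 76151706 to 76153858, between genes and 40.8 kb from a start of Nufip1, with a signal value of 51.1. The next was on chromosome 9 from 67631665 to 67634853, 72.0 kb from the nearest GENCODE start of Tln2, where the RefSeq annotation places a start of that gene. The next on chromosome 4 from 46304045 to 46305777, in an intron of the antisense gene Gm12446 and 37.8 kb from Foxe1, lay at a RefSeq start of Gm12447. The others lay on chromosome 15 from 57974724 to 57977188, 8.23 kb from Fam83a and at a RefSeq start of an unnamed gene, and on chromosome 2 from 166785806 to 166787442, 5.09 kb from Trp53rkb.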

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

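The counts of peaks given here were chosen after the data had been seen. A group of 2 samples is too small for a test of outlying samples, and there was 1 group, so no effect could differ between groups. Peaks that entered no comparison of protein-coding genes were counted instead; any more than a few peaks exceed the limit that a count of 0 allows, so the counts are descriptions and test nothing. On unplaced sequences there were 16 replicated peaks, on 6 sequences, with a median width of 601 bp and a highest signal value of 32.8. At the starts of non-coding genes or pseudogenes alone there were 1966 replicated peaks, which are part of the 54.0% at promoter windows, with a median width of 814 bp and a median signal value of 7.30.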

How the results depend on the processing

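Among the alternatives, the RefSeq starts, the background matched on number of starts, the domains counted once and the background without receptor genes were chosen after the data had been seen. Of 170 alternative values of the main results 122 kept their direction and stayed within the spread or 1.5 times the main count, and 48 moved. No paired analysis was possible because there was 1 group. Except where the construction shows it (fewer peaks, a stricter overlap, another distance), the cause was not tested. With only peaks at or above the median signal value, 95.5% of replicate 1 and 86.7% of replicate 2 peaks were shared, rho was 0.925, 99.1% of pooled peaks were kept and 76.4% of those overlapped both replicates, 84.4% of peaks were at starts, 10.3% lay away from them and 64.3% of genes were marked. With −log10 q of at least 5 these were 94.5%, 85.2%, 0.934, 97.7%, 75.8%, 60.4%, 26.2% and 68.1%, and 2 lists were narrower. An overlap of 50% of either peak gave 72.4% and 63.8% shared and a rho of 0.946; 50% of both peaks gave 59.1%, 54.9% and 0.950, with 74.9% of kept peaks overlapping both replicates. The pooled list had 41.0% of peaks at starts and 35.7% away from them, 69.9% of genes marked and 2 lists narrower. Without replicate 1 or replicate 2 the share at starts was 44.1% to 47.7%, genes marked 68.8% to 69.2%, the share away from starts 30.2% to 33.9%, and 2 lists were narrower. A window of 500 bp gave 51.1% at starts and 68.0% of genes marked; 2500 bp gave 62.0%, 69.7% and 1 narrower list. The outermost start alone gave 44.6% at starts, 65.1% of genes marked and 39.6% away. A distance of 10000 bp left 20.2% away from starts, and RefSeq starts added to GENCODE 24.8%. A gap of 0 bp gave 4 narrower lists, and at a gap of 3000 bp 6 lists were over-represented in the widest 5%, 4 of the 10 main ones with neural progenitor and Hox genes. In the widest 1%, 2 lists were over-represented, those of cardiac transcription factors and sarcomere genes. With matching on CpG decile 6 lists were marked more often, of which calcium handling, smooth muscle and erythroid genes had not passed before. Single lists that changed direction were pluripotency (wider by 1933 bp, which passed the test), erythroid (-29.0 percentage points marked, which passed) and Hox genes (-10.4) with peaks at or above the median signal value, and epicardium in the widest 5% at a gap of 0 bp (-5.01). Hox genes were wider by 1832 bp at a gap of 3000 bp, which passed. Both pluripotency and Hox genes were called narrower at −log10 q of at least 5 and at a gap of 0 bp, so the direction of their widths turned with the setting. With CpG matching, neural progenitor (-4.28) and ribosomal genes (-1.65) fell below their background in marked share and sarcomere genes lay 2.90 above it in signal value. Endothelium was at -1.01 in the widest 1%. The 10 wider lists were all called under each alternative but for housekeeping with the outermost start. Depth was not given, so weak peaks of 1 replicate cannot be said to be absent from the other.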

Other observations

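The tests of CpG content, of peak height, of erythroid signal, of the strength of peaks found in 1 replicate and of lists with low CpG were chosen after the result was seen. The match on number of starts was chosen after the data had been seen. Genes of heart muscle, smooth muscle and red blood cells were marked more often than others among promoters poor in CpG. In the lowest 3 deciles of the CpG ratio 730 of 6582 protein-coding genes were marked, or 11.1%, but 12 of 12 sarcomere genes (adjusted p = 1.2e-11), 7 of 7 genes of mature cardiac metabolism (adjusted p = 5.5e-07), 5 of 5 smooth muscle genes (adjusted p = 3e-05), 9 of 12 erythroid genes (adjusted p = 8.6e-07) and 4 of 6 calcium handling genes (adjusted p = 0.00294) were, by Fisher's exact test with Benjamini-Hochberg adjustment over 11 lists. These deciles held 1057 olfactory receptor genes, 1 of them marked, and 323 vomeronasal receptor genes, 0 of them marked, which lower the 11.1%. Leaving out the olfactory receptor genes alone gave 13.2%. None of the 12 macrophage genes in these deciles and 2 of 10 skeletal muscle genes were. The widest domains among all marked genes of these deciles were those of Abi3 with Gngt2 (15.5 kb), Eno3 (13.9 kb), Myh6 (12.4 kb), Actc1 (10.2 kb), Hrc (9.20 kb), Mybpc3 (8.97 kb), Gpsm3 (8.93 kb), Prrt2 (8.48 kb), Myl2 (7.91 kb), Tnnc1 (7.83 kb), Pln (7.48 kb), Hspb7 (7.47 kb) and Tnni1 (7.20 kb), named after their values were seen. Eno3 had 8.94 and 7.95 kb in the single replicates, and in replicate 2 Abi3 with Gngt2 had 8.43 kb and Prrt2 2.96 kb. The domain of Abi3 with Gngt2 was also that of Phospho1, whose CpG ratio of 0.645 lay outside these deciles. Its width is therefore not that of promoters poor in CpG alone. Whether the other domains were joined to those of neighbouring starts was not tested. In the highest 2 deciles 15 of 4388 genes were unmarked, among them the histone genes Hist1h2bq, Hist1h2ao, Hist1h2ap and Hist1h2br, which have close copies.

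Promoter windows of non-coding genes held peaks as well. Of antisense genes 40.5% were marked, of lincRNA genes 19.1% and of processed pseudogenes 3.10%. A peak counts for every window it meets, so these shares include peaks at nearby starts of protein-coding genes. Marked antisense genes had a median width of 2312 bp, near the 2363 bp of protein-coding genes. The imprinted non-coding genes Airn, Kcnq1ot1, H19 and Meg3 were all marked, in domains of 6.28, 6.05, 3.98 and 3.88 kb, and were named after their values were seen. Of the peaks over 5000 bp from a GENCODE start, 798 lay within 1000 bp of a RefSeq start.

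The wide domains of cardiac transcription factor and sarcomere genes were set against 3 technical explanations. Both lists were put together after their widths had been seen, so the p-values here describe a set picked for its width. The 48 genes had a median of 7.16 kb, which was 4.99 kb above random marked genes of the same CpG decile, 4.78 kb above genes with a similar number of annotated starts and 4.98 kb above genes of similar peak height (n = 48 genes, each p = 0.0002 against random lists, the smallest they can give). Each comparison argues against that property as the whole cause. No biological explanation was tested, since the series holds 1 tissue at 1 stage.

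Erythroid promoters were marked 44.2 percentage points more often than genes of the same CpG decile (82.4% against 38.2%, n = 17 genes, p = 0.0002 against random lists, the smallest they can give), which argues against CpG content as the cause. The single replicates had 12 and 15 of the 17 genes marked. With only peaks at or above the median signal value, erythroid genes were marked less often than all other protein-coding genes (difference -29.0 points). That background was not matched on CpG ratio, so the matched difference under this filter is unknown. Blood cells held in the heart are a candidate source and predict low signal. The marked genes had a median signal value of 7.53 against 16.2 in CpG-matched marked genes (difference -8.63, n = 14 genes, p = 0.0388 against random lists), just under a central range that began at 7.86, and the difference did not pass adjustment over all lists. The globin genes were weak, since Hbb-bh1 and Hba-x (named after its value was seen) had signal values of 3.72 and 4.15, Hbb-y was marked in replicate 2 alone, and the near-identical copies Hba-a1 and Hba-a2, in neither, are uncertain. Of the 17 genes 1, Tal1, is also in the endothelial list, and no test separated blood cells from weak marking in heart cells.

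Peaks found in replicate 1 alone had a median GC content of 53.8% and those in replicate 2 alone 51.2%. Within quintiles of −log10 q the difference was 2.60 percentage points (95% bootstrap interval 2.40 to 2.74), so unequal −log10 q does not account for it. The lists of the replicates were called apart at unknown depth, so equal −log10 q need not mean equal strength. Unequal strength as a cause therefore stays open. A GC bias between the libraries might also account for the difference. Across shared regions the rank in replicate 1 minus that in replicate 2 had a rho of 0.0752 with GC. This lay between the bounds set for and against such a bias. At this value the bias cannot be told apart from other differences between the pools. No biological explanation was tested.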
